A study of Mus musculus with 8 samples.

How the data were processed

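ChIP-seq libraries came from JM8.N4 mouse embryonic stem cells, grown without feeders in serum and LIF, cross-linked with formaldehyde and sonicated, per the labels' protocols. Of 8 libraries (2 lines, each with input, control IgG, CTCF and Smc3), 4 had a peak list. The input and IgG libraries were not analysed here as libraries of their own. Groups came from the sample labels. The extraction protocol in the labels names antibodies against Rad21 and CTCF, whereas the antibody label of each Smc3 library names Smc3, and the latter was followed. Reads were single-end, per the labels' protocols.

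The submitters' processing notes name CASAVA, FastQC 0.10.1, Bowtie 0.12.8, MACS2 2.1.0.20140616, deepTools 2.4.1 and the mouse build mm10, with no role or order. Which control library, threshold, duplicate filter or fragment length was used for peak calling is not given in the sources used here. Each list was numbered as 1 library, and pooling is not mentioned in the labels. The 4 lists had 10 columns in the layout of a MACS2 table and no header. Positions counted from 1, since length equalled end minus start plus 1 in every row, and no peak overlapped another of its list. The pileup signal at each summit is the authors' value, deposited as whole numbers in the WT lists and in steps of 0.961 and 0.772 in the C59 CTCF and Smc3 lists. The p-value and q-value of each peak were deposited by the authors on a linear scale, with largest q-values of 0.0495, 0.0374, 0.0474 and 0.0490 in WT CTCF, C59 CTCF, WT Smc3 and C59 Smc3. A p of exactly 0, too small to write, stood in 3206 WT and 2345 C59 CTCF peaks. The fold enrichment, a ratio of pileup to local background, is also the authors' deposited value. It was used only to describe, rank or filter peaks within a list, since pileups of the lists were scaled differently. Peak length and summit position were deposited by the authors in bp.

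The background at each summit was computed as pileup plus 1, divided by fold, minus 1. A Poisson p from that background lay within 0.1 on the log10 scale of the deposited p for 97.9% of C59 CTCF peaks and 100% of those of the other lists. The floor of a list, taken as the median background in its lowest decile of background, gives the genome-wide level at which the list was called. Divided by the pileup step, the floor gives the depth of the library relative to the others. That use assumes the same fragment length, genome size and background formula in all 4 lists; the narrowest peak was 250 bp in each. Numbers of peaks depend on this depth and on the strength of each immunoprecipitation, so a shorter list does not by itself mean fewer bound sites.

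Peak lists were compared by position with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Shares carry exact Clopper-Pearson intervals at 95%. Chance overlap was the mean over 100 shifts of one list along each chromosome, in steps of 0.5 Mb up to 50 Mb. Deciles of fold were taken within a list, and shares at the same distribution of fold were weighted means over the 10 deciles. With 1 library per line and protein no test between conditions was made, no p-value across genes or peaks is given, and no value has a standard deviation.

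Gene positions came from the NCBI RefSeq table of the GRCm38.p6 assembly, which has the chromosomes of mm10. That table was used without strand or exons, and no genome sequence was used. The planned windows around start sites therefore became windows around either annotated end of a gene, summits were placed at a gene end, inside a gene or outside genes with no split into exons and introns, peaks were named by the nearest gene end, and the planned CTCF motif search was not run. A gene had a peak when a summit lay within 1 kb of an end, and the strongest such peak by fold gave its value. Of 330 listed symbols in 13 lists, all matched the table, 2 of them by synonym, and the olfactory list was made of all 1110 genes whose symbol begins with Olfr. Shares of lists were ranked among 10000 random lists of protein-coding genes of the same size. The share of WT genes found again in C59 was ranked among 10000 draws matched on the decile of WT fold.

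Comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names 10 genes in every case (Ctcf, Rad21, Smc3, Smc1a, H19, Pou5f1, Sox2, Nanog, Xist and Myc). From each list and for each protein it takes up to 2 members with the highest WT fold among those with a peak in both lines, and up to 2 with a peak in 1 line alone. Genome-wide it takes the 3 strongest peaks of both lines, of WT alone and of C59 alone for each protein. Not every gene so named is described, and some items are not reported here. Wapl and Espl1, outside the rule, were named after their values were seen, to complete a count of 4. Alternatives covered the overlap rule, the q threshold, equal numbers of strongest peaks, the chromosomes used and the width of the gene end window. For equal numbers the strongest peaks were those with the smallest deposited p, with ties ordered by fold. Alternatives added after seeing the data left out chromosomes 1, 8, 11, X and Y, took the CTCF list of the other line, and counted different peaks in place of genes. Whether a peak at a gene in 1 line alone overlapped a peak of the other line was also asked after seeing the data. A pair of tests that set fold across lists, both bearing on the number of C59 Smc3 peaks, were run and left out, because fold describes peaks within a list only.

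The overlap code was tested on simulated data with known shares: on 96324 simulated peaks made from the WT CTCF autosomal list every share was recovered with a gap of 0 percentage points. The simulated peaks were that list's own peaks, moved by less than their width, so this checks the code alone. Chance overlap by shifting was 5.02% where random positions gave 5.02%. The shifted list was itself made of random positions, so chance levels for clustered peaks were not checked. Of 500 random gene lists, 5.4% fell outside the central 95%.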

Results

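Chromatin immunoprecipitation and sequencing (ChIP-seq) located CTCF and the cohesin subunit Smc3 in mouse embryonic stem cells of the JM8.N4 line. CTCF is a zinc finger protein that binds DNA at insulators and loop boundaries. Cohesin is the ring complex, built on Smc1a, Smc3 and Rad21, that holds sister chromatids together and extrudes chromatin loops. Wild-type (WT) cells were compared with C59, a knock-in line in which all copies of CTCF carry a FLAG epitope and a HaloTag and all copies of Rad21 carry a SNAPf tag and a V5 epitope. Both self-labelling tags bind dyes covalently and are used for imaging proteins in live cells. The comparison asks whether CTCF and cohesin occupied the same places in the tagged line as in the wild type. Each line gave 1 library each of input, control IgG, CTCF and Smc3, so there were no replicates, and no difference between the lines could be set against a spread. Peak lists of the 4 CTCF and Smc3 libraries were analysed.

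The WT CTCF list held 98759 peaks covering 62031.6 kb, and the C59 CTCF list held 82227 peaks covering 48828.3 kb, 83.3% of the WT number. For Smc3 the lists held 47281 peaks over 24027.3 kb in WT and 25734 peaks over 10952.1 kb in C59, 54.4% of the WT number. Median peak widths were 550 bp and 537 bp for CTCF and 463 bp and 398 bp for Smc3, in WT and C59. The lists carried no read totals. The floor of the background that the pileups and fold enrichments imply was 4.27 for WT CTCF, 3.56 for C59 CTCF, 4.16 for WT Smc3 and 3.56 for C59 Smc3. Set on one scale with the step between pileup values, these floors gave a C59 to WT ratio of library depth of 0.869 for CTCF and 1.11 for Smc3, if fragment length and genome size were set alike for all 4. Intervals below are exact 95% Clopper-Pearson intervals and cover counting error only. A place with no peak was below the authors' threshold, which does not show that the protein was absent.

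CTCF sites of the tagged line were, with few exceptions, sites of the wild type. Of the C59 CTCF peaks, 97.1% (97.0 to 97.2) overlapped a WT CTCF peak by at least 1 bp, against 4.99% by chance, and 2378 did not. In the other direction, 79.8% of WT CTCF peaks (79.6 to 80.1) were found in C59, against 4.16% by chance, which left 19907 seen in WT alone. The peaks missing from C59 were the weak ones. WT peaks found again had a median fold enrichment of 12.9, and those seen in WT alone 4.17. In the weakest decile of the WT list 24.3% were found in C59, in the fourth decile 82.3%, in the seventh 9875 of 9876, and in each of the 3 strongest deciles 100%.

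**Figure D1:**
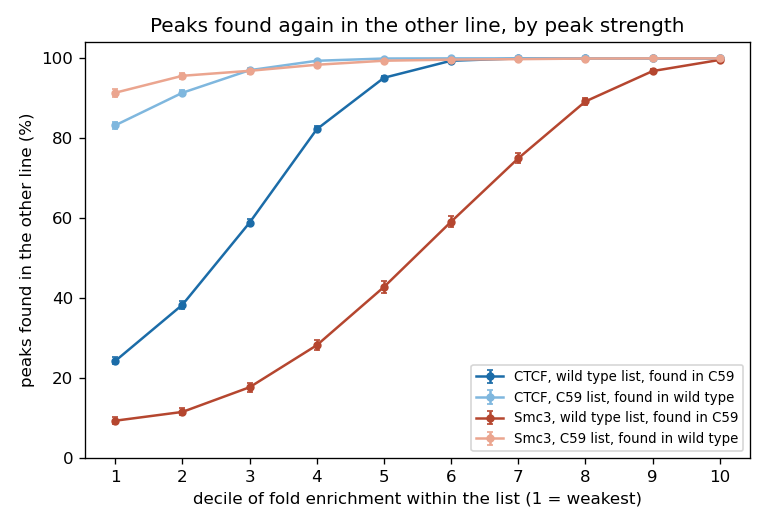
Share of peaks found in the other line (percent, vertical axis) by decile of fold enrichment within each list (horizontal axis, 1 is the weakest), for the CTCF and Smc3 lists of both lines; bars are exact 95% intervals. WT CTCF peaks climb from 24.3% in the weakest decile to 100% in the strongest, WT Smc3 peaks from 9.35% to 99.6%, and both C59 lists stay above 83.2%.

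Among the strongest CTCF peaks of the WT list, 2 that stood in C59 as well lay on chromosome 2 at 19414238 to 19415682, outside genes and nearest to Msrb2 (fold 64.8 in WT and 61.2 in C59), and on chromosome 2 at 128411999 to 128413364, outside genes and nearest to Spdye4c (63.2 and 62.7). Each also carried Smc3 in both lines. The strongest WT peaks with no C59 counterpart were far weaker, with folds of 14.1 inside Pde4c on chromosome 8, 12.7 inside Heatr5a on chromosome 12 and 12.7 inside Etv6 on chromosome 6. The strongest C59 peaks with no WT counterpart had folds of 9.09 nearest to Smim23 on chromosome 11, 8.71 nearest to Ccnl1 on chromosome 3 and 8.64 inside B4galt6 on chromosome 18. Folds are the authors' own values for each peak and describe strength within a list.

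At the genes that make up this machinery, CTCF occupancy was found in both lines at Smc3 (chromosome 19, fold 23.3 in WT and 26.1 in C59), at Ctcf itself (chromosome 8, 5.69 and 4.87), at Esco1, a cohesin acetyltransferase (49.3 and 62.8), and at Pds5b, a cohesin regulator (36.3 and 27.5). Smc1a (fold 3.51) and Pds5a (5.13) had a CTCF peak in WT alone, and Rad21 had none at its ends in either line. In all, 11 of 22 machinery genes carried a CTCF peak at a gene end in WT and 8 in C59. Among 24 pluripotency genes the counts were 13 and 11. Lefty1 (18.9 and 26.0) and Nodal (18.4 and 13.1), secreted proteins of the TGF-beta family, and Nanog (7.87 and 6.96), a core pluripotency factor, had a peak in both lines, while Zfp42 (6.61), on chromosome 8, and Sall4 (4.09) had one in WT alone. Pou5f1 and Sox2 had no CTCF peak at their ends, with 4 and 2 WT peaks within 10 kb.

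Chromosomes did not share alike in the overlap. In C59, 87.3% of the WT CTCF peaks on chromosome 1 were found (86.5 to 88.1), 82.7% of those on chromosome 11 (81.9 to 83.5) and 71.6% of those on chromosome 8 (70.4 to 72.8), while the other 16 autosomes ranged from 77.3% to 81.2%. Peaks of those 3 chromosomes also stood on a raised background in 1 of the lines or in both. The background at chromosome 8 was 1.36 times that of other autosomes for WT CTCF and 1.00 times for C59 CTCF. At chromosome 1 it was 1.00 times in WT and 1.36 times in C59, and at chromosome 11 it was 1.19 times in WT and 1.45 times in C59. Genes named here on those chromosomes share this limit. Without them and the sex chromosomes the share found again was 79.6%.

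**Figure D2:**
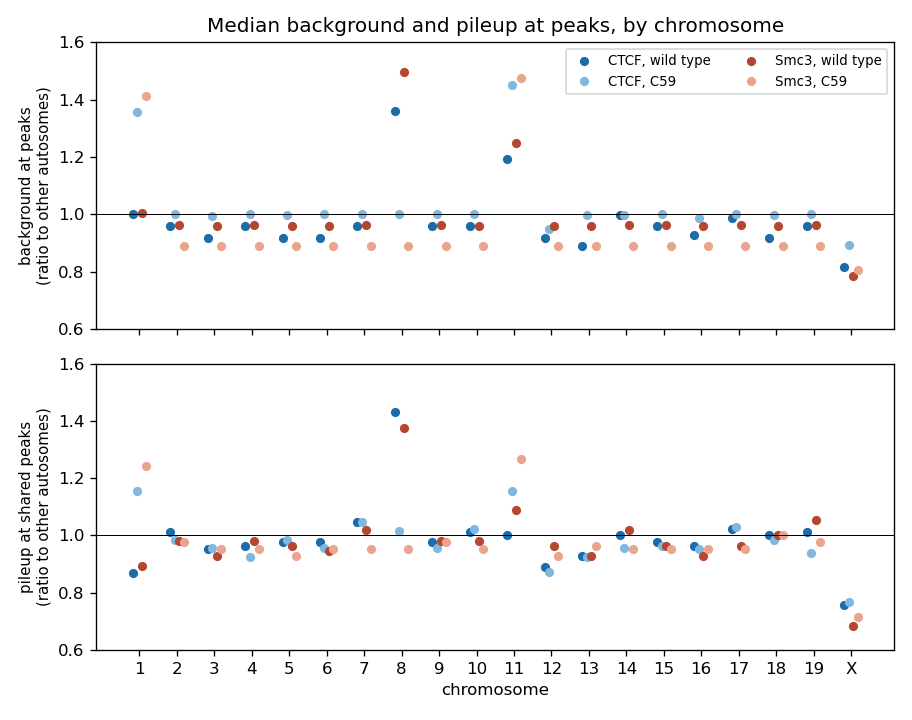
Median background at peaks (upper panel) and median pileup at peaks shared by both lines (lower panel), each as a ratio to the other autosomes, by chromosome, for the 4 libraries; each point is 1 library. Chromosome 8 stands at 1.36 and 1.5 in the WT CTCF and Smc3 backgrounds, chromosome 1 at 1.36 and 1.41 in those of C59.

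Smc3 was found at fewer places in C59 than in the wild type, and nearly all of those places were Smc3 sites of the wild type too. Of the C59 Smc3 peaks, 98.1% (97.9 to 98.3) overlapped a WT Smc3 peak, against 1.85% by chance, and 483 did not. In the other direction, 52.9% of WT Smc3 peaks (52.5 to 53.4) were found in C59, against 1.02% by chance, and 22246 were seen in WT alone. Where Smc3 was missing from C59, CTCF as a rule was not, since 86.3% of those 22246 sites (85.9 to 86.8) held a C59 CTCF peak. Among the 78852 WT CTCF peaks found in both lines, Smc3 was present in both lines at 30.8%, in WT alone at 23.2% and in C59 alone at 0.321%.

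Strength again set apart the Smc3 sites of both lines from those of WT alone, with median folds of 8.33 and 4.24. The share found in C59 climbed from 9.35% in the weakest WT decile to 42.8% in the fifth, 89.2% in the eighth and 99.6% in the strongest. The strongest WT sites lay on chromosome 7 at 143706352 to 143707360 inside Osbpl5 (fold 41.5 in WT and 18.9 in C59), on chromosome 1 at 135752544 to 135753601 at a gene end of Csrp1 (40.3 and 20.0), and on chromosome 14 at 122060584 to 122061372 nearest to Timm8a2 (38.5 and 23.8). Those with no C59 peak were led by a site at a gene end of Akt1, a growth factor signalling kinase (15.5), a site nearest to Rap1gap (13.9) and a site at a gene end of Abhd16a (13.6), all 3 with CTCF in both lines. Strong sites of C59 alone included those nearest to Ppm1h (7.15) and nearest to Actl7b (6.81). When each list was held to its 25734 strongest peaks by p, 83.4% of the WT Smc3 peaks were found in C59 and 91.1% of the WT CTCF peaks, so the shares above depend on the lengths of the lists. Chromosome 1 (64.7%) and chromosome 11 (59.5%) lay above the other 16 autosomes (48.7% to 55.5%), and chromosome 8 (45.4%) and X (35.1%) below.

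Pluripotency genes with Smc3 at a gene end numbered 11 of 24 in WT and 5 in C59. Tbx3 (6.10 in WT and 3.93 in C59) and Klf2 (4.75 and 4.62), on chromosome 8, transcription factors of the naive state, carried Smc3 in both lines, as did Sox2 (4.08 and 4.78), although the strongest Sox2 and Tbx3 peaks of the lines stood at opposite gene ends and those at Klf2 did not overlap. Dppa5a (7.23), Nodal (5.70) and Nanog (3.24) had a peak in WT alone. Of the 11 WT genes, 4 (36.4%) had Smc3 in C59, against an average of 28.5% for genes matched on fold, a percentile of 73.2. That share lay inside the central 95% of the matched draws, but 11 genes are too few to exclude a greater loss. A gene counted if any C59 peak lay at an end, whether or not that was the WT site. Within 10 kb of Nanog there were 9 Smc3 peaks in WT and 4 in C59, and within 10 kb of Pou5f1 5 and 4. None of the 4 machinery genes with Smc3 in WT, which were Smc3 itself (4.62), Esco1 (6.05), Wapl and Espl1, had it in C59. Genes matched on fold averaged 31.6%, which puts 0 of 4 at percentile 9.985, inside the central 95%. Within 2500 bp 0 of 6 had Smc3 in C59, against a matched average of 33.4%, a percentile of 2.915. Within 10000 bp 9 of 14 had it in C59. The growth regulator Myc had Smc3 in WT alone (7.21), with 7 Smc3 peaks within 10 kb in WT and 2 in C59, whereas CTCF stood there in both lines (14.3 and 12.7). Its relative Mycn (22.6 and 9.43) and the tumour suppressor Trp53 on chromosome 11 (19.8 and 6.70) had Smc3 in both lines, while the C59 Smc3 peak at Cdk4, a cell cycle kinase (5.80), overlapped a WT peak (2.55) whose summit lay beyond 1 kb of the gene end.

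Smc3 peaks lay on CTCF peaks in both lines. In WT 95.2% of Smc3 peaks (95 to 95.4) overlapped a CTCF peak of the same line, against 4.65% by chance, and in C59 97.9% did (97.7 to 98.1), against 3.54%. CTCF peaks overlapped Smc3 less often, with 44.3% (43.9 to 44.6) in WT and 30.0% (29.7 to 30.4) in C59, against 2.22% and 1.11% by chance. CTCF sites with Smc3 were the stronger ones, with a median fold of 21.1 against 5.64 for those without in WT. Of the 43701 WT CTCF sites with Smc3, 42609 were found in C59, against 65.8% of sites without Smc3, but at the same distribution of fold the shares were 80.1% and 79.8%. The control behind each list is not given in the sources used here, and if the lists of a line shared one, a part of the overlap within that line may come from it. Against the CTCF list of the other line the overlap was 92.8% for WT Smc3 and 98.0% for C59 Smc3. Under a rule that asked for 50% of both peaks, 66.3% of WT and 52.4% of C59 Smc3 peaks overlapped CTCF and 16.4% of C59 CTCF peaks overlapped Smc3. Among the 25734 strongest peaks of each list, 77.9% of WT and 75.6% of C59 CTCF peaks overlapped Smc3.

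Smc3 sites without CTCF were few and weak, and lay at gene ends more often than those with CTCF. There were 2267 in WT with a median fold of 3.32, against 6.01 for Smc3 sites with CTCF, and 542 in C59 with 3.89 against 5.73. A gene end lay within 1 kb of 29.7% of them in WT (27.9 to 31.7), against 9.13% of Smc3 sites with CTCF, and of 52.2% in C59 (47.9 to 56.5), against 8.21%. In the other line 14.4% of the WT sites and 63.1% of the C59 sites were found as Smc3 peaks. For WT the low share went with the low fold of most of these sites. In the weakest decile, which held 1199 of the 2267 sites, 8.67% were found, against 9.58% of sites with CTCF. In the fifth decile 66.7% of 48 sites (51.6 to 79.6) were found, against 42.6% with CTCF. The sixth, seventh, eighth and ninth deciles held only 19, 12, 8 and 2 sites without CTCF. The share found was above that with CTCF in each of them. In the seventh, eighth and ninth its interval spanned the share with CTCF, so these deciles do not set the shares apart. Weighted equally over 9 deciles, as the strongest held no such site, the share without CTCF was 57.7%. Deciles with few sites carried the same weight there as the others. For WT sites with CTCF the weighted share was 52.9% over all 10. That includes the strongest decile, where 99.6% were found, so 57.7% and 52.9% are not at the same distribution of fold. For C59 the share at the same distribution of fold was 83.1%, against 98.8% of sites with CTCF.

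CTCF and Smc3 peaks stood at gene ends about 3 times as often as chance positions. Summits within 1 kb of either end of a protein-coding gene made up 9.39% of WT CTCF peaks (9.21 to 9.57), 9.35% of C59 CTCF peaks (9.15 to 9.55), 10.1% of WT Smc3 peaks (9.85 to 10.4) and 9.14% of C59 Smc3 peaks (8.79 to 9.50), against 3.17% to 3.19% at shifted positions. A further 48.0%, 47.2%, 43.6% and 40.8% lay elsewhere inside genes, and the remaining 42.6%, 43.5%, 46.3% and 50.0% outside them. Of 21627 protein-coding genes, 38.8% had a WT CTCF peak at an end, 33.3% a C59 CTCF peak, 21.0% a WT Smc3 peak and 11.3% a C59 Smc3 peak. Where a gene had such a peak in 1 line alone, that peak overlapped a peak of the other line at 78 of 1472 genes for WT CTCF, 98 of 281 for C59 CTCF, 33 of 2249 for WT Smc3 and 49 of 146 for C59 Smc3, so a part of the genes of C59 alone comes from the window.

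The clustered protocadherins, cell surface proteins that give neurons their identity, had the highest share of genes with CTCF of the 14 gene lists in both lines. Of 58 genes, 56 had CTCF at an end in WT and 57 in C59, and 53 had Smc3 in WT and 33 in C59. Genes of the Pcdha and Pcdhg groups share an end, so that these genes stood for 51, 46, 35 and 12 different peaks. Pcdhgb1 (41.8 in WT and 32.4 in C59) and Pcdhgb7 (41.5 and 43.9) had the strongest WT CTCF peaks among genes with CTCF in both lines, Pcdhb10 (12.6 and 7.92) and Pcdhga12 (9.73 and 9.15) the strongest WT Smc3 peaks among genes with Smc3 in both lines. The strongest Pcdhga12 peak of C59 stood at the opposite, shared end of the gene, and at the WT site Pcdhga12 had a C59 fold of 7.14. Pcdhb1 had CTCF in C59 alone (5.06), and Pcdhb17 (6.36) was among the 20 genes with Smc3 in WT alone. Of the 53 WT genes, 33 (62.3%) had Smc3 in C59, against an average of 58.9% for genes matched on fold, a percentile of 72.1. At a −log10 q of at least 10 that percentile was 100, and with equal numbers 99.6. The draws counted genes as if independent, so a peak at a shared end counted once for each gene. By peak, 3 of 11 WT Smc3 peaks were found in C59 for Pcdha, 10 of 27 for Pcdhb and 9 of 26 for Pcdhg. These percentiles therefore do not show that Smc3 sites were kept more often here. Across the Pcdha genes, on chromosome 18 from 36930285 to 37188897, there were 11 Smc3 peaks in WT and 3 in C59, while CTCF peaks numbered 21 and 16.

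**Figure D3:**
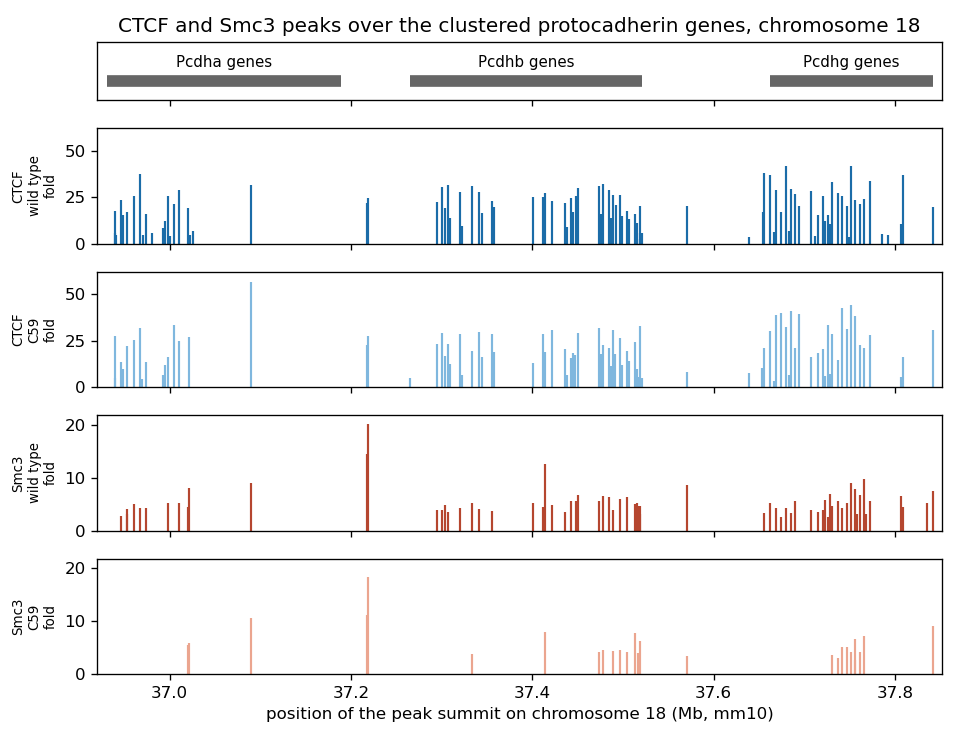
Peaks across the Pcdha, Pcdhb and Pcdhg genes of chromosome 18 (build mm10), with the summit position in Mb on the horizontal axis and the authors' fold enrichment within each list as line height; grey bars are the spans of the listed genes. CTCF shows 97 peaks in WT and 88 in C59 over the region, Smc3 69 and 26.

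Hox genes, which pattern the body axis, had CTCF at 15 of 39 genes in WT and 10 in C59, and Smc3 at 9 and 5. Hoxa10 (45.3 and 42.7) and Hoxc10 (45.1 and 41.7) had the strongest WT CTCF peaks among genes with CTCF in both lines, and both had Smc3 in WT alone (6.41 and 6.62). Hoxc5 (18.7 and 13.8) and Hoxb5 (13.7 and 8.70), the latter on chromosome 11, had Smc3 in both lines, while Hoxa13 (5.61) and Hoxb7 (4.91), on chromosome 11, had CTCF in WT alone. The share of Hox genes with WT CTCF that had it in C59, 66.7%, stood at percentile 1.76 among genes matched on fold, which averaged 82.1%. It stood inside the central 95% with wider windows, a stricter q or equal numbers of peaks.

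Ribosomal protein genes had Smc3 nearly as often in C59 as in WT. Of 32 genes, 22 had Smc3 at an end in WT and 20 in C59, and 20 had CTCF in each line. Rpl3 (9.50 in WT and 5.95 in C59) and Rps18 (7.93 and 9.69) had the strongest WT Smc3 peaks among those with Smc3 in both lines, at opposite ends of the gene for Rpl3, and Rps3 (4.52) had it in WT alone. The C59 peak at Rps15 (3.57) overlapped a WT peak (7.80) whose summit lay beyond 1 kb of the gene end. Of the 22 WT genes, 18 (81.8%) had Smc3 in C59, against an average of 42.5% for genes matched on fold, a percentile of 100. The match was on fold alone and not on whether the Smc3 peak overlapped CTCF. Both proteins were counted by gene, so their peaks need not stand at the same site. CTCF was found in C59 at 19 of the 20 WT genes, led by Rplp0 (40.1 and 40.8) and Rpl11 (38.5 and 18.7), with a matched average of 96.3%. Rps18 had CTCF in WT alone (4.02).

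**Figure D4:**
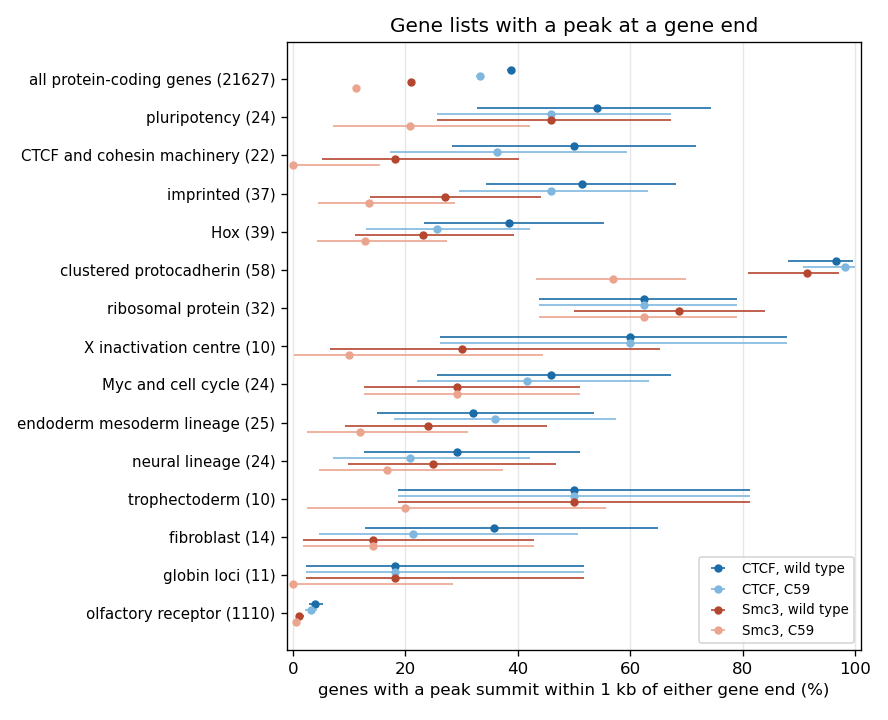
Share of genes with a peak summit within 1 kb of either gene end (percent, horizontal axis) for all protein-coding genes and the 14 lists (list size in parentheses), in the 4 libraries; bars are exact 95% intervals. Protocadherins reach 96.6% with WT CTCF and 56.9% with C59 Smc3, ribosomal protein genes 68.8% and 62.5% with Smc3 in WT and C59, and olfactory receptors at most 3.96%.

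Imprinted genes, expressed from one parental copy, had CTCF at 19 of 37 in WT and 17 in C59, and Smc3 at 10 and 5. Kcnk9 (25.3 and 47.8) and Magel2 (30.5 and 29.9) carried CTCF in both lines and Smc3 in both lines (14.8 and 15.9, 13.6 and 6.84). Rtl1 (8.36) and Peg3 (5.53) had CTCF in WT alone, and H13 (4.52) had Smc3 in WT alone. H19 had no peak at its ends, with 3 peaks within 10 kb in each of the 4 lists. At the X inactivation centre 6 of 10 genes had CTCF in each line, and 3 and 1 had Smc3. Xist, the RNA that silences the X, had CTCF in both lines (16.0 and 10.5) and Smc3 in WT alone (5.23), and Ftx had CTCF (23.7 and 21.7) and Smc3 (4.84 and 4.28) in both. Over the whole X, 35.1% of WT Smc3 peaks were found in C59, against 48.7% to 55.5% on 16 autosomes. Smc3 missing at genes of the X in C59 shares this limit. The Myc and cell cycle list had CTCF at 11 of 24 genes in WT and 10 in C59, led by Trp53 (44.0 and 21.0) and Mycn (38.9 and 29.7), and Smc3 at 7 in each line.

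Genes of other cell types were occupied as well. CTCF stood at 8 and 9 of 25 endoderm and mesoderm genes, 7 and 5 of 24 neural genes, 5 and 5 of 10 trophectoderm genes and 5 and 3 of 14 fibroblast genes, in WT and C59. Smc3 stood at 6 and 3, 6 and 4, 5 and 2, and 2 and 2 of them. Among the strongest were Mesp1, a mesoderm factor (CTCF 45.4 and 59.2), Olig2, a glial and motor neuron factor (CTCF 40.7 and 43.6, Smc3 19.5 and 11.9), Nes, the intermediate filament nestin (CTCF 35.4 and 37.5, Smc3 22.3 and 12.9), Ets2 (CTCF 36.2 and 38.9) and the collagen gene Col1a1 on chromosome 11 (CTCF 40.0 and 63.7, Smc3 33.2 and 24.3). Eomes, a factor of both mesoderm and trophectoderm, had Smc3 in WT alone (5.80), and its C59 CTCF peak (13.3) overlapped a WT peak (30.4) whose summit lay beyond 1 kb of the gene end. Globin loci had CTCF at 2 of 11 genes in each line, the 2 Hbq1 genes on chromosome 11, with Smc3 there in WT alone (6.01 at Hbq1a). Olfactory receptor genes were nearly bare, with CTCF at 44 of 1110 in WT and 35 in C59 and Smc3 at 13 and 6, all at percentile 0 of random lists.

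Set against 10000 random lists of the same size, 3 of the 14 lists lay outside the central 95% for CTCF in each line, 5 for WT Smc3 and 4 for C59 Smc3. Protocadherin, ribosomal protein and olfactory receptor genes did so in all 4 libraries. Pluripotency genes (percentile 99.7) and trophectoderm genes (97.6) did so for WT Smc3, and Myc and cell cycle genes (99.1) for C59 Smc3. The 3 lists first named did so under all settings, but the pluripotency call was lost at a −log10 q of at least 10 and with equal numbers, the trophectoderm call with equal numbers, and the Myc and cell cycle call with windows of 2500 and 10000 bp and at that q. Neighbouring genes of a cluster share peaks and gene length was not matched, so these percentiles describe the lists and are not tests between the lines.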

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

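All tests of the background of chromosomes and of the number of Smc3 peaks were chosen after the values they measure had been seen in part; those of the ribosomal protein genes were written before their results were seen. That a chromosome must not pass the mark for copy number in the other line as well was added after chromosome 11 had been seen.

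Chromosomes 1, 8 and 11 came up because the background under their peaks, a quantity outside the peak comparison itself, stood above that of other autosomes in 1 line or both. On chromosome 8 it was 1.36 times that of other autosomes in WT CTCF and 1.5 times in WT Smc3, against 1.00 and 0.890 in C59. On chromosome 1 it was 1.36 in C59 CTCF and 1.41 in C59 Smc3, against 1.00 and 1.00 in WT. On chromosome 11 it was 1.45 in C59 CTCF and 1.47 in C59 Smc3, against 1.19 and 1.25 in WT.

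Stronger binding sites on chromosome 8 as such are argued against by the pileup at shared CTCF sites there, 1.43 times that of other autosomes in WT and 1.02 times in C59. A single depth or scaling factor is argued against by chromosome 1, where 87.3% of WT CTCF peaks were found in C59, above the 81.2% of the highest of 16 other autosomes. A candidate explanation is a difference in chromosome copy number, extra copies of chromosome 8 in the WT culture and of chromosome 1 in C59, since 100% of the 13 stretches of 10 Mb of chromosome 8 in WT (46.2% in C59) and 100% of the 20 of chromosome 1 in C59 (75% in WT) stood above the median stretch of those 16 autosomes. For chromosome 11 the explanation stays open, because 100% of its 13 stretches passed that mark in C59 and 100% in WT, so the test does not separate the lines. No biological explanation by the tags was tested, and a culture difference cannot be separated from the line with 1 library each.

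The C59 Smc3 list held 54.4% of the number of WT Smc3 peaks. Fewer reads in the C59 Smc3 library are argued against by its estimated depth before scaling, 1.11 times that of WT, and gain or loss of whole chromosomes by the 52.3% of WT Smc3 peaks found in C59 on the 16 other autosomes alone. A lower depth at calling stays open, because the C59 pileups appear scaled down to the control and the floor at which the list was called was 0.856 times that of WT. For CTCF a ratio of 0.835 went with 83.3% of the WT number of peaks. That does not settle what such a drop costs Smc3, whose WT peaks had a median pileup of 38, against 59 for WT CTCF. A lower sensitivity at all sites, from less cohesin bound or from a weaker Smc3 immunoprecipitation in C59, is consistent with the 99.6% of the strongest WT decile that was found in C59, since the missing peaks were the weaker ones. Less bound cohesin, which the tag on Rad21 could bring, and a weaker immunoprecipitation would both give this and cannot be separated with 1 library per line, and how much a lower depth at calling adds was not measured.

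Ribosomal protein genes had Smc3 in C59 more often than other genes of the same WT fold. Chance choice of the listed genes is argued against by the 45 ribosomal protein genes outside the list, where 20 of 25 genes with WT Smc3 (80%) had it in C59 against 36.3% for matched genes, a percentile of 100. Gain of chromosomes 1 and 11 in C59 is argued against too, as without chromosomes 1, 8, 11 and X the share was 84.2%, which is 43.0 percentage points above that of matched genes. Signal without cohesin at strongly transcribed genes, which any immunoprecipitation can give, stays open. Smc3 without CTCF stood at 5.15% of 408 tRNA genes in WT (3.21 to 7.76). That interval spans the 3.32% of protein-coding genes. In C59 the shares were 0% of tRNA genes and 1.54% of protein-coding genes. Gene length, and so the overlap of the windows at both ends, was not matched. Whether the Smc3 peak overlapped CTCF was not matched either. In the fifth decile of WT fold, 66.7% of Smc3 sites without CTCF were found in C59, against 42.6% with CTCF. In the weakest decile the shares were 8.67% and 9.58%. How this bears on the matched share was not tested. Of classes chosen after the data had been seen, ribosomal protein genes had Smc3 without CTCF at 39.0% of 77 in WT. Histone genes had it at 43.8% of 16 in each line (19.8 to 70.1). Proteasome subunit genes had it at 1 of 40 in WT and 0 in C59. The control IgG libraries, which bear on such signal, were not analysed here, and so a preference of cohesin for ribosomal protein genes is a hypothesis with no test of its own.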

How the results depend on the processing

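Alternatives that left out chromosomes 1, 8, 11, X and Y or used the CTCF list of the other line were chosen after seeing the data. Shares are given in the order WT CTCF found in C59, C59 CTCF found in WT, WT Smc3 found in C59, C59 Smc3 found in WT, Smc3 with CTCF in WT and C59, and CTCF with Smc3 in WT and C59. With an overlap of 50% of both peaks they were 77.2%, 92.8%, 46.4%, 85.3%, 66.3%, 52.4%, 31.7% and 16.4%. With summits within 100 bp they were 76.4%, 91.8%, 49.9%, 91.7%, 85.9%, 92.0%, 41.1% and 28.8%. At a −log10 q of at least 10 they were 82.0%, 97.4%, 49.6%, 98.6%, 99.4%, 99.3%, 38.2% and 22.8%. At 5, C59 CTCF found in WT stayed within its interval and the others were 80.7%, 54.6%, 98.4%, 97.8%, 98.8%, 42.1% and 28.6%. With the 25734 strongest peaks of each list they were 91.1%, 91.6%, 83.4%, 84.4%, 79.5%, 77.5%, 77.9% and 75.6%. Without chromosomes 1, 8, 11, X and Y the first 4 were 79.6%, 97.4%, 52.3% and 98.4%, and the last 4 stayed within their intervals. On numbered autosomes alone only C59 CTCF with Smc3 left its interval, at 30.4%, and merging touching peaks changed none. With the CTCF list of the other line Smc3 with CTCF was 92.8% in WT and within its interval in C59. Under each setting that was run for both, a smaller share of WT Smc3 than of WT CTCF peaks was found in C59. The cause was not tested, except that equal numbers shorten the CTCF lists most and a 50% rule bears on peaks of unequal width.

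Summits at a gene end, in the order WT CTCF, C59 CTCF, WT Smc3 and C59 Smc3, made up 5.78%, 5.74%, 6.16% and 5.47% within 500 bp, 17.9%, 17.9%, 18.9% and 17.9% within 2500 bp, and 9.10%, 9.12%, 8.65% and 8.30% at a −log10 q of at least 10. Lists outside the central 95% numbered 5 for C59 CTCF and 7 for C59 Smc3 with a window of 2500 bp, 7 for WT CTCF, 6 for C59 CTCF and 8 for WT Smc3 with 10000 bp, and 3 for WT Smc3 with equal numbers, and stayed within 1.5 times otherwise. Among the other values, for named genes and single lists, 577 were unchanged or inside their interval, 167 were higher and 36 lower. At a −log10 q of at least 10, the named genes with a peak went from 51 to 42 for WT CTCF, 36 to 33 for C59 CTCF, 48 to 39 for WT Smc3 and 26 to 18 for C59 Smc3. With equal numbers they went to 24, 23 and 29 for the first 3, and C59 Smc3, the shortest list, kept its 26. The percentile of the ribosomal protein genes in Smc3 found again ran from 98.9 to 100 over these settings. The CTCF motif alternatives were not run, because no genome sequence was used. No paired analysis was possible because each line had 1 library per protein and no result came from a test. Depth was estimated and not varied, so its share in the loss of weak peaks, of which 24.3% were found in C59 in the weakest WT CTCF decile, was not tested.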

Other observations

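Gene classes below were chosen after the data had been seen, and their shares describe these libraries. Smc3 without a CTCF peak stood at an end of 30 of 77 ribosomal protein genes in WT (39.0%, interval 28.0 to 50.8) and 34 in C59 (44.2%, 32.8 to 55.9). The corresponding share of all protein-coding genes was 3.32% in WT and 1.54% in C59. Of 16 histone genes with symbols of the older style, 7 had such a peak in each line (43.8%, 19.8 to 70.1). Genes for translation factors with the symbol Eif had it at 3 of 55 in WT and 5 in C59, proteasome subunit genes at 1 of 40 and 0, and Nduf genes of the respiratory chain at 4 of 40 and 1.

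Vomeronasal receptor genes had CTCF at 8 of 355 genes in each line (2.25%, 0.978 to 4.39) and Smc3 at 2 and 1. Keratin genes had CTCF at 10 of 49 in each line. Zinc finger genes with the symbol Zfp had CTCF at 40.8% of 397 in WT and 33.2% in C59, beside 38.8% and 33.3% of all protein-coding genes. Genes for long noncoding RNAs had CTCF at an end in 25.8% of 12697 in WT and 22.3% in C59, and Smc3 in 14.6% and 8.47%. tRNA genes had CTCF at 123 of 408 in WT and 115 in C59, and Smc3 at 102 and 42.

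The Hbb globin cluster on chromosome 7, from 103812524 to 103853207, had no peak in any of the 4 lists. The Hoxb cluster on chromosome 11 had 21 CTCF peaks in WT and 14 in C59, while Hoxc had 10 in each and Hoxd 9 in each. The site with the highest Smc3 fold of the protocadherin region, on chromosome 18 at 37218024 to 37218933, lay between the Pcdha and Pcdhb genes, with a fold of 20.2 in WT and 18.3 in C59.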
